A study of Mus musculus with 18 samples.

How the data were processed

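The series holds 18 libraries of poly(A) RNA from primary cultures of mouse sensory neurons, in 6 groups of 3. Per the labels' protocols, dorsal root ganglia (DRG) or trigeminal ganglia (TGN) were taken from C57BL/6 mice at postnatal day 5, dissociated, and cultured for 7 days with nerve growth factor and with cytarabine, a drug that kills dividing cells. DRG cultures were exposed for 6 h to SERPINE1 protein at 20 µg/ml. TGN cultures were exposed for 6 h to Pam3CSK4, a synthetic triacylated lipopeptide that the labels call a TLR1/2 agonist, at 1 µg/ml, or to FSL-1, a synthetic diacylated lipopeptide that they call a TLR2/6 agonist, at 1 µg/ml. Each exposure has 3 control libraries of its own, which the sample labels call untreated, whereas the design text speaks of vehicle controls for the lipopeptides. Random hexamers primed the reverse transcription and the libraries were sequenced as DNA nanoballs on an MGISEQ-2000, per the labels. The labels do not state whether the 3 replicates of a group were separate cultures or came from different animals, so they may be technical.

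The authors deposited 1 table per experiment with expected counts per gene, per the file headers, and these were not scaled between libraries. Between 8.19% and 32.1% of the values in a library were not whole numbers: 8.19% to 8.81% in the Pam3CSK4 experiment, and 29.7% to 32.1% in the others. The deposited tables also hold FPKM, scaled by the authors within each library. In the FSL-1 table the headers name the unit. In the other tables the unit is inferred from the values: gene lengths implied by counts and deposited values differed from those of the FSL-1 table by a median ratio of 1.00 for the SERPINE1 table (5th to 95th percentile 0.945 to 1.04) and 0.948 for the Pam3CSK4 table (0.841 to 1.02). The FSL-1 table also holds TPM, per the file headers, scaled by the authors to the same sum in every library. HISAT, HISAT2, Bowtie2 2.2.5, RSEM 1.2.8 and the genome build GRCm38.p6 are named in the submitters' processing notes, with no role or order. Annotation release and strand setting are not given. Of the genes listed, 99.3% in each table matched an NCBI gene identifier of the GRCm38.p6 annotation, from which the coordinates were taken.

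Library totals, in units of 1e6 counts, ranged from 21.8 to 22.6 in the DRG experiment, from 17.8 to 18.1 in the Pam3CSK4 experiment and from 19.2 to 19.5 in the FSL-1 experiment. Between 17362 and 18434 genes had at least 1 count in a library. The 10 genes with the most counts took 3.32% to 5.40% of a library. Without molecular identifiers, counting intervals and floors cover counting error only.

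Groups were set from the titles and labels before the data were examined, as were the comparisons, the tests, the gene lists, the rule for named genes and most of the alternatives. Each exposure was compared with its own controls. Expected counts were rounded, genes were filtered with filterByExpr, libraries were scaled with TMM, and the edgeR 4.0.16 quasi-likelihood test (glmQLFit, glmQLFTest) was run in R 4.3.3 on the 6 libraries of each comparison. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and genes with an absolute log2 fold change of at least 1 were counted as well. The difference between the lipopeptides was tested on the 12 trigeminal libraries, in 4 groups, as the Pam3CSK4 response minus the FSL-1 response, each against its own controls. All tests are two-sided. Rose, fell and changed are used of genes past the threshold. CPM values are counts scaled to 1e6 per library with TMM factors, over the tested genes for group means and over all genes for single libraries, so the latter do not average exactly to the former. Errors are the standard error (SE) of the fitted log2 fold change or the standard deviation (SD) of CPM, with n = 3 libraries per group.

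The 18 gene lists and 11 cell type marker lists were tested with camera (limma 3.58.1), two-sided, with a preset correlation of 0.01, where at least 3 members were measured, and again with a correlation estimated from the libraries. Benjamini-Hochberg ran over the lists of a comparison. Called members were also counted with p-values adjusted over the list alone. The lists are textbook sets and share some genes; none was chosen on these libraries. Overlaps were tested with Fisher's exact test over genes tested in both comparisons, beside the number that independent lists would share. Named genes were Plaur, Plau, Serpine1, Tlr1, Tlr2 and Tlr6. The rule added, per comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 counts and no overlap between groups, without gene models and pseudogenes. It also took up to 4 members of each list with the smallest p and, for the difference, 6 genes per direction. Where a group held at most 3 counts, a fold is given with its 95% counting interval, or, for a group at 0, against a floor of 3 counts over the group.

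Alternatives fixed with the design were DESeq2 size factors in edgeR, library totals alone, DESeq2 1.42.0, limma-voom, no low-count filter, a mean of at least 50 counts, limma on log2 of FPKM or TPM with a pseudocount of 1 or 0.1 (values of at least 1 in at least 3 libraries), a block on the replicate number, all 12 trigeminal libraries in 1 fit, an estimated list correlation, fry, and leaving out each replicate. Added after the data were seen were a correction for transcript length, a correction for length and GC content (lowess, span 0.3, per library), FPKM without a filter, leaving out pairs of libraries that stood apart, and a macrophage marker score as a covariate. Marker lists for skeletal muscle, stratified epithelium and cerebellar neurons were also added then. They split into genes already seen and held-out genes.

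The tests were tested on simulated data, counts with 200 changed genes per comparison. Of genes changed by 1.5, 2 and 4 fold that were tested, edgeR recovered 14.9%, 61.2% and 95.5% in the SERPINE1 design, among 15081 genes. It recovered 27.7%, 69.2% and 95.4% in the Pam3CSK4 design, among 14791 genes, and 64.2%, 83.3% and 98.5% in the FSL-1 design, among 14750 genes. For the difference it recovered 26.2%, 72.7% and 83.1%, among 15250 genes. False calls were 8 of 122, 16 of 141, 19 of 182 and 5 of 124, so the share exceeded the nominal 5% in the 3 single comparisons. With DESeq2 the shares of false calls were 20.9%, 29.8%, 14.7% and 16.3%. In each design camera found the 5 simulated raised lists among 20 and no other list. The simulated genes were drawn independently of each other, so this cannot show how camera behaves where the genes of a list are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.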

Results

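Primary cultures of mouse sensory neurons were profiled after 6 h with SERPINE1, with the lipopeptide Pam3CSK4 or with the lipopeptide FSL-1, each in 3 libraries beside 3 control libraries. Cultures came from dorsal root ganglia (DRG) for SERPINE1 and from trigeminal ganglia (TGN) for the lipopeptides, and the labels do not state whether replicates were separate cultures or animals. The RNA is of whole cultures, which also held transcripts of other cells. Lyz2, the macrophage lysozyme, named after its values were seen, was at 131 CPM or more in every library. Changes are therefore those of the culture and cannot be assigned to neurons. The series title names PLAUR, the urokinase receptor, together with TLR2 and chronic itch, and the comparisons ask how each ligand changes transcript levels. In the GRCm38.p6 annotation, Plaur (NCBI gene 18793) lies on chromosome 7 from 24460937 to 24475970, and Tlr2 (gene 24088) on chromosome 3 from 83836272 to 83841824. Plau (gene 18792) lies on chromosome 14 from 20836662 to 20843388, and Serpine1 (gene 18787) on chromosome 5 from 137061504 to 137072272. Tlr1 (gene 21897) and Tlr6 (gene 21899) are neighbours on chromosome 5, from 64924680 to 64933600 and from 64953092 to 64970942.

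DRG cultures exposed to SERPINE1, an inhibitor of plasminogen activators, had higher Tlr2 and lower Plaur transcript levels than their controls. Tlr2, a receptor for bacterial lipoproteins, was 14.5-fold higher, at 20.6 ± 11.1 against 1.41 ± 0.379 CPM (SD, n = 3), with a log2 fold change of 3.86 ± 0.44 (SE, adjusted p = 0.000736, edgeR quasi-likelihood). Plaur was 1.45-fold lower, at 36.7 ± 1.19 against 53.3 ± 0.925 CPM, with a log2 fold change of -0.54 ± 0.07 (adjusted p = 0.00109, edgeR quasi-likelihood), and was lower in 3 of 3 treated libraries. Plau, the urokinase gene, Serpine1, Tlr1 and Tlr6 did not pass, with log2 fold changes of 0.06 ± 0.19, 0.13 ± 0.38, 0.17 ± 0.52 and 0.60 ± 0.36. The Plau value turned to -0.29 (adjusted p = 0.0280, edgeR quasi-likelihood) without control 1 and treated replicate 3. Both libraries stood apart from their groups, and without them treatment coincides with that split of the libraries.

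Inflammatory genes made up most of the largest rises with SERPINE1. Of 24 measured NF-kB subunits and feedback targets, 21 rose and 0 fell, both over all genes and adjusted over the list alone. Their median log2 fold change was 1.62, with Nfkbiz at 4.48, Ier3 at 2.37 and Zc3h12a at 1.96 (camera adjusted p = 1.10e-15, and adjusted p = 0.487 with an estimated correlation). Of 20 chemokines, 10 rose and 0 fell, and 12 rose adjusted over the list alone, with Cxcl2 at 5.87, Cxcl1 at 5.25 and Cxcl3 at 4.55 (camera adjusted p = 0.00604, and adjusted p = 0.656 with an estimated correlation). The interferon response list had 24 of 29 members risen and 0 fallen, the same numbers adjusted over the list alone, with Rsad2 at 5.21 and Irgm1 at 2.97 (camera adjusted p = 7.20e-13, and adjusted p = 0.656 with an estimated correlation). Among inflammatory effectors, 12 of 18 rose, also adjusted over the list alone, with Acod1, which makes itaconate, at 5.50 (camera adjusted p = 0.00152, and adjusted p = 0.656 with an estimated correlation). Among cytokines, 7 of 17 rose and 1 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0892). Tnf showed the largest rise among named genes, at 8.08 ± 1.53, with 11.2, 14.3 and 152 CPM in the treated libraries and at most 0.230 CPM in the controls. Its call ended with limma-voom (adjusted p = 0.102), and DESeq2 gave no adjusted p for Tnf. Treated replicate 3 was also high for Cxcl2, at 92.2 CPM against 19.4 and 24.8 in replicates 1 and 2. Without it Tnf stood at 5.83, Cxcl2 at 4.79, Cxcl3 at 3.76 and Acod1 at 4.42, and all passed (adjusted p of at most 0.000420).

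SERPINE1 also raised immediate early genes and sterol genes. Of 29 immediate early genes, 23 rose and 1 fell, 24 and 1 adjusted over the list alone, with a median of 1.79 and with Dusp6 at 2.73, Fosl2 at 2.25 and Fosl1 at 2.21 (camera adjusted p = 4.44e-16, and adjusted p = 0.0941 with an estimated correlation). Of 22 cholesterol synthesis genes, 15 rose and 2 fell, 16 and 2 adjusted over the list alone, with Insig1 at 1.76 and Hmgcr, the rate-limiting enzyme, at 1.18 (camera adjusted p = 0.000108, and adjusted p = 0.656 with an estimated correlation). In the unfolded protein and integrated stress response list, 12 of 23 rose and 1 fell, 13 and 2 adjusted over the list alone, with Slc7a11, a cystine transporter, at 2.99 and Trib3 at 2.42 (camera adjusted p = 0.00152, and adjusted p = 0.656 with an estimated correlation). Of 23 STAT3 targets, 11 rose and 3 fell, 12 and 3 adjusted over the list alone, with Cebpd at 2.78 and Socs3 at 2.35 (camera adjusted p = 0.00169, and adjusted p = 0.656 with an estimated correlation). The axon injury and regeneration list had 8 of 24 members risen and 4 fallen, also adjusted over the list alone, with Klf6 at 2.29 and Sox11 at 2.15. Its median was -0.02 while its mean was 0.39 and its test pointed up (camera adjusted p = 0.0202, and adjusted p = 0.656 with an estimated correlation).

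Respiratory chain genes and some neuronal genes fell with SERPINE1. In the neuronal identity list, 12 of 28 fell, 1 rose and 15 did not pass, also adjusted over the list alone, with Elavl4 at -0.66, Ntrk1, the nerve growth factor receptor, at -0.59, and Isl1 risen at 1.51 (camera adjusted p = 0.00534, and adjusted p = 0.656 with an estimated correlation). In the nuclear-encoded respiratory chain list, 21 of 22 fell, and 22 fell adjusted over the list alone, with Ndufa2 at -0.71 and Ndufb5 at -0.58 (-0.23 and -0.20 after correction for transcript length; camera adjusted p = 5.16e-08, and adjusted p = 0.656 with an estimated correlation). Of 36 measured itch receptors, channels and peptides, 2 rose and 7 fell, 2 and 6 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0892). Nppb, a peptide of itch neurons, was at -0.83 ± 0.16 (adjusted p = 0.00605, edgeR quasi-likelihood), and Calca, which encodes CGRP, at -0.72 ± 0.11 (adjusted p = 0.00204, edgeR quasi-likelihood). The itch receptor genes Mrgpra3 at -1.57 and Mrgprx1 at -1.06, named after their values were seen, also fell. Across genes, fold changes followed transcript length, with a Spearman correlation of 0.337 over 15251 genes, which are not independent replicates. The median was -0.59 for transcripts under 500 nt and 0.34 for those over 6000 nt. After correction for length, 13 of the 22 respiratory chain genes were fallen with a median of -0.24 in place of -0.47, Nppb stood at -0.40 (adjusted p = 0.0405) and Calca at -0.41 (adjusted p = 0.0102).

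Markers of other cell types moved with SERPINE1 as well. Of 11 endothelial markers, 8 rose, also adjusted over the list alone, with a median of 2.79, but the list did not pass (camera adjusted p = 0.121). Cdh5, the endothelial cadherin, stood at 3.27, 4.28 and 5.49 CPM in the controls and at 130, 111 and 8.96 CPM in treated replicates 1, 2 and 3. Pecam1, named after its values were seen, stood at 69.7, 57.6 and 1.73 CPM in the treated libraries. Sox18, an endothelial transcription factor and 1 of the 8 largest rises, stood at 25.8, 25.7 and 1.42 CPM. With limma-voom, the calls of Cdh5 and Sox18 ended (adjusted p = 0.0960 and 0.145). Of 19 macrophage markers, 1 fell and 18 did not pass, 0 fell adjusted over the list alone, and the median was -0.74 (camera adjusted p = 0.0377, and adjusted p = 0.723 with an estimated correlation). The macrophage score split by library as well, at -0.38, 0.82 and 0.72 in controls 1, 2 and 3 and at -1.02, -0.71 and 0.58 in treated replicates 1, 2 and 3 (log2, centred). Among the remaining marker lists, satellite glia had 5 of 15 risen with Sox2 at 3.48 (camera adjusted p = 0.0892), Schwann cells 2 risen and 4 fallen of 15 (0.153), dividing cells 9 of 15 risen (0.0623), fibroblasts 1 fallen of 14 (0.354) and mural cells 1 risen of 10 (0.870).

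**Figure D1:**
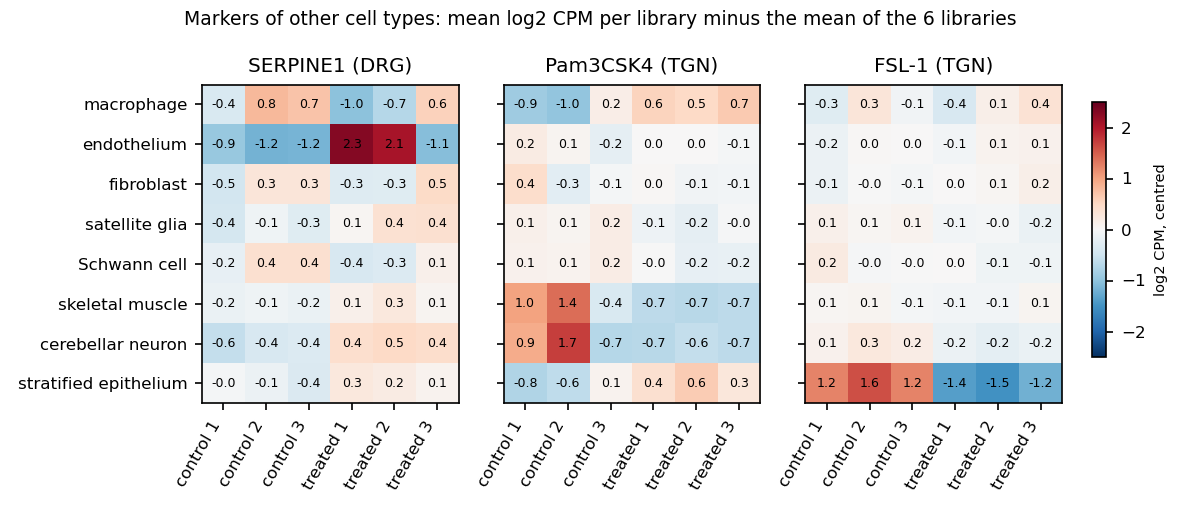
Marker scores of 8 cell types per library, as the mean log2 CPM of the markers minus the mean of the 6 libraries of each experiment. Endothelial markers are high in 2 of the 3 SERPINE1 libraries, muscle and cerebellar markers in controls 1 and 2 of the Pam3CSK4 set, and epithelial markers in the FSL-1 controls.

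Over all 15251 genes tested, 4103 rose and 3164 fell with SERPINE1, and 2033 of these changed by at least 1 log2 unit, 1924 upward and 109 downward (edgeR quasi-likelihood, adjusted p under 0.05). The 8 largest falls included Fndc5 at -2.01, Adra2c, a noradrenaline receptor, at -1.65, and Hbegf, a growth factor, at -1.46. The groups did not overlap for 57.5% of genes, where chance gives 10%. The balance of directions is not fixed: DESeq2 gave 3740 up and 3785 down, and the length correction 3433 up and 3717 down. No list call held with an estimated correlation.

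TGN cultures exposed to Pam3CSK4 had higher Tlr2, Plaur and Serpine1 levels than their controls. Tlr2 was 21.6-fold higher, at 147 ± 6.21 against 6.81 ± 3.95 CPM, with a log2 fold change of 4.43 ± 0.34 (adjusted p = 0.000375, edgeR quasi-likelihood). Plaur was 1.80-fold higher, at 48.7 ± 0.917 against 27.1 ± 7.07 CPM, with a log2 fold change of 0.85 ± 0.17 (adjusted p = 0.0279, edgeR quasi-likelihood), and was higher in 3 of 3 treated libraries. Serpine1 was at 1.36 ± 0.19 (adjusted p = 0.00646), Tlr1 at 2.83 ± 0.39 (adjusted p = 0.00633), Plau 2.83-fold higher (SE 0.29 on the log2 scale, adjusted p = 0.0247) and Tlr6 at 1.30 ± 0.29 (adjusted p = 0.0368). The Plaur call ended without control 1 (0.79, adjusted p = 0.0947) and without treated replicates 1, 2 or 3 (0.84, 0.84 and 0.86, adjusted p = 0.103, 0.119 and 0.116), and the value was 0.48 (adjusted p = 0.00662) without controls 1 and 2. The calls of Plau and Tlr6 ended without each library but control 3, with adjusted p from 0.0666 to 0.109 for Plau and from 0.0839 to 0.145 for Tlr6. Without controls 1 and 2, Plau stood at 0.85 (adjusted p = 0.000502).

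**Figure D2:**
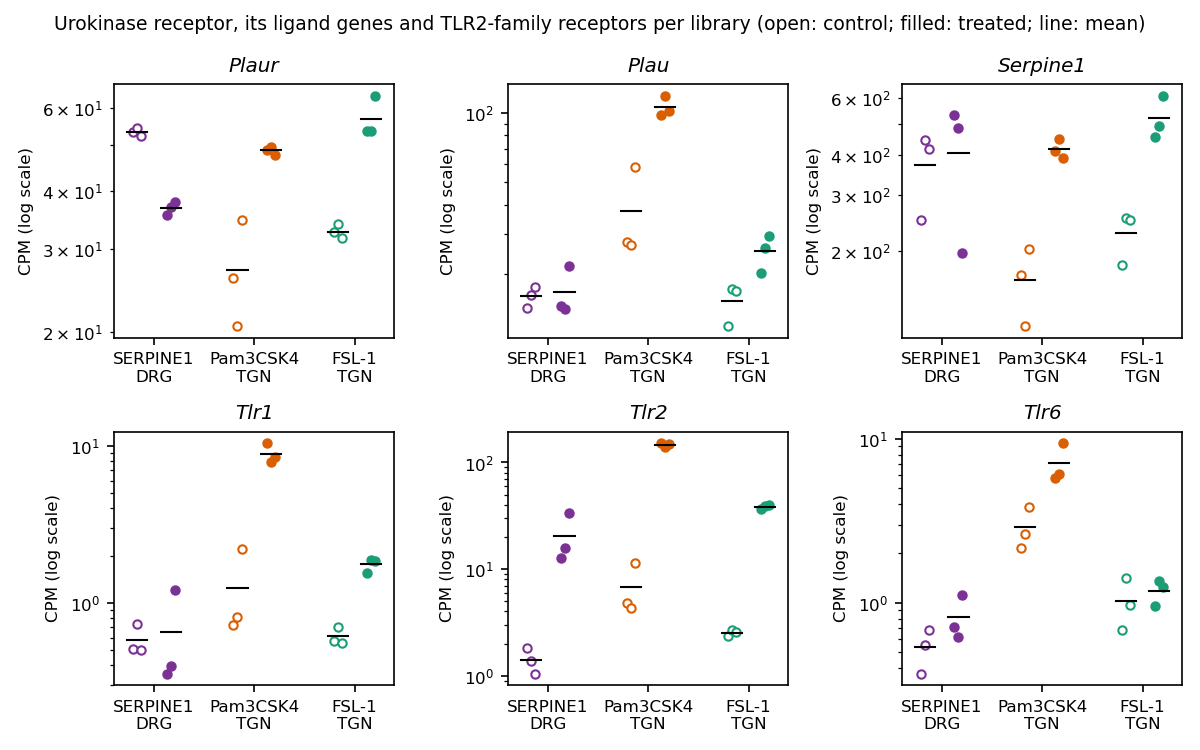
CPM on a log scale of the 6 genes fixed in advance, in each library of the 3 experiments (open for controls, filled for treated libraries, lines for means). Plaur is lower with SERPINE1 (36.7 against 53.3 CPM) and higher with Pam3CSK4 (48.7 against 27.1 CPM) and FSL-1 (56.9 against 32.7 CPM).

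Chemokines, cytokines, interferon response genes and NF-kB genes rose together with Pam3CSK4. All 29 measured interferon response genes rose, also adjusted over the list alone, with a median of 2.13, Rsad2 at 4.20 and Cmpk2 at 3.54 (camera adjusted p = 4.06e-143, and adjusted p = 0.00941 with an estimated correlation). Of 25 NF-kB genes, 23 rose, 24 adjusted over the list alone, with Vcam1, an adhesion molecule, at 3.58 and Nfkbie at 2.30 (camera adjusted p = 5.42e-67, and adjusted p = 0.0304 with an estimated correlation). Of 25 chemokines, 18 rose, 22 adjusted over the list alone, with a median of 2.73 and Cxcl3 at 7.05, Cxcl2 at 6.57 and Cxcl1 at 3.78 (camera adjusted p = 2.25e-51, and adjusted p = 0.0241 with an estimated correlation). Of 20 cytokines, 15 rose, 17 adjusted over the list alone, with Il1b at 7.94 ± 0.17, Tnf at 6.20 and Il1a at 4.33 (camera adjusted p = 5.16e-36, and adjusted p = 0.0234 with an estimated correlation). Among inflammatory effectors, 21 of 22 rose, 22 adjusted over the list alone, with Acod1 at 7.91, Nos2, the inducible nitric oxide synthase, at 7.82 and Ptx3 at 2.96 (camera adjusted p = 1.01e-54, and adjusted p = 0.0237 with an estimated correlation). Fpr1, a formyl peptide receptor, was 186-fold higher (95% counting interval 51.2 to 1542), with 2 counts over the controls.

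The Toll-like receptor list had 8 of 24 members risen, 12 adjusted over the list alone, with Irak3 at 1.40 and Tlr3 at 1.00 (camera adjusted p = 1.25e-07, and adjusted p = 0.354 with an estimated correlation). The urokinase list had 6 of 18 risen, 8 adjusted over the list alone, with Serpinb2, a further plasminogen activator inhibitor, at 2.10 (camera adjusted p = 0.000667, and adjusted p = 0.370 with an estimated correlation). Of 25 STAT3 targets, 10 rose, 15 up and 1 down adjusted over the list alone, with Il6 at 3.18 and Ccl2 at 2.84 (camera adjusted p = 3.80e-07, and adjusted p = 0.105 with an estimated correlation). Of 34 sensory neuron ion channels, 4 fell, 6 adjusted over the list alone, with a median of -0.36 and Kcna2, a potassium channel, at -1.22 ± 0.09 (camera adjusted p = 6.00e-06, and adjusted p = 0.370 with an estimated correlation). The neuronal identity list had 2 of 28 fallen, also adjusted over the list alone, and a median of -0.41 (camera adjusted p = 0.000149, and adjusted p = 0.481 with an estimated correlation). Markers of cerebellar neurons, a list added after the data were seen, scored 0.92 and 1.73 in controls 1 and 2, -0.72 in control 3 and from -0.69 to -0.59 in the treated libraries (log2, centred), and their part in the falls of these lists was not tested. Of 34 itch genes, 5 rose, 5 up and 1 down adjusted over the list alone, and the list did not pass (camera adjusted p = 0.438). Among the 5 were Nppb at 0.73 and Calcb at 0.85. The Nppb call ended without each library but control 3 (adjusted p from 0.101 to 0.156), and the Calcb call without controls 1 or 2 or treated replicates 2 or 3 (adjusted p = 0.106, 0.0965, 0.0848 and 0.110).

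Markers of other cells moved with Pam3CSK4. Of 19 macrophage markers, 6 rose, 18 adjusted over the list alone, with a median of 0.99 (camera adjusted p = 1.27e-08, and adjusted p = 0.370 with an estimated correlation). Csf1r, the macrophage growth factor receptor, stood at 22.3, 23.8 and 43.9 CPM in controls 1, 2 and 3 and between 77.8 and 86.8 CPM in the treated libraries. Its log2 fold change of 1.46 ± 0.24 lost its call without each treated replicate (adjusted p = 0.0625, 0.0591 and 0.0818) and was 0.90 without controls 1 and 2. The 8 largest falls included the skeletal muscle genes Atp2a1 at -1.86, Cacna1s at -1.87 and Obscn at -1.83. Atp2a1 stood at 219, 299 and 93.3 CPM in the controls and between 51.6 and 63.1 CPM in the treated libraries. These 3 calls ended without each library but control 3 (adjusted p from 0.0559 to 0.142 for Atp2a1, from 0.0559 to 0.155 for Cacna1s and from 0.0526 to 0.149 for Obscn), and without controls 1 and 2 the values were -0.74 for each. Duox1, an oxidase, fell by 1.96 on the log2 scale and kept its call without any 1 library. Satellite glia had 1 of 15 fallen (camera adjusted p = 0.0456), Schwann cells 0 of 15 (0.0233), neutrophils 1 of 4 risen (0.0219), dividing cells 0 of 15 (0.00389), fibroblasts 0 of 13 (0.438), endothelium 0 of 10 (0.674) and mural cells 1 of 10 fallen (0.674), with a median of 0.21 and a mean of -0.04. With an estimated correlation, the adjusted p of the first 4 of these were 0.250, 0.239, 0.383 and 0.618.

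Over all 14913 genes tested, 898 rose and 430 fell with Pam3CSK4, and 494 changed by at least 1 log2 unit, 425 upward and 69 downward (edgeR quasi-likelihood, adjusted p under 0.05). Across genes, fold changes followed transcript length, with a Spearman correlation of -0.200 over 14913 genes. They also followed GC content, at -0.228 over the 99.1% of these genes with a GC value. After correction for both 821 rose and 240 fell. The total of 1328 depends on single libraries: it was 588, 661 and 5491 without controls 1, 2 and 3, and 453, 408 and 384 without treated replicates 1, 2 and 3. DESeq2 called 2264 genes, and the fit of all 12 trigeminal libraries called 3539, of which 45.8% were up in place of 67.6%.

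TGN cultures exposed to FSL-1 also had higher Tlr2, Plaur and Serpine1 levels than their controls. Tlr2 was 15.1-fold higher, at 38.4 ± 2.04 against 2.54 ± 0.169 CPM, with a log2 fold change of 3.92 ± 0.09 (adjusted p = 2.37e-08, edgeR quasi-likelihood). Plaur was 1.74-fold higher, at 56.9 ± 5.80 against 32.7 ± 1.12 CPM, with a log2 fold change of 0.80 ± 0.08 (adjusted p = 0.000252, edgeR quasi-likelihood), and was higher in 3 of 3 treated libraries. Serpine1 was at 1.19 ± 0.14 (adjusted p = 0.000799) and Tlr1 at 1.51 ± 0.24 (adjusted p = 0.00465), while Tlr6 did not pass at 0.21 ± 0.30. Plau was at 0.72 ± 0.16 (adjusted p = 0.0326). Its call ended without control 1, control 3 or treated replicates 2 or 3 (adjusted p = 0.0647, 0.0714, 0.129 and 0.115), and with FPKM, TPM or the fit of 12 libraries (adjusted p from 0.0513 to 0.240).

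Chemokines and inflammatory effectors showed the largest rises with FSL-1. Of 20 chemokines, 16 rose, 17 adjusted over the list alone, with a median of 2.17 and Cxcl5 at 6.84 ± 0.10, Ccl5 at 6.37 and Cxcl2 at 4.36 (camera adjusted p = 2.32e-130, and adjusted p = 0.00948 with an estimated correlation). Among inflammatory effectors, 16 of 18 rose, 17 adjusted over the list alone, with Nos2 at 6.13 and Acod1 at 5.61 (camera adjusted p = 4.90e-99, and adjusted p = 0.00570 with an estimated correlation). Of 25 NF-kB genes, 21 rose, 22 adjusted over the list alone, with Vcam1 at 3.79 and Nfkbiz at 1.87 (camera adjusted p = 9.99e-84, and adjusted p = 0.0133 with an estimated correlation). Of 29 interferon response genes, 21 rose, 24 adjusted over the list alone, with a median of 0.59 and Gbp5 at 4.25 and Gbp2 at 2.52 (camera adjusted p = 6.66e-90, and adjusted p = 0.00570 with an estimated correlation). Of 17 cytokines, 12 rose, 14 adjusted over the list alone, with Tnf at 3.08, Tslp, an itch-related cytokine, at 2.97 and Il6 at 2.69 (camera adjusted p = 2.80e-24, and adjusted p = 0.0378 with an estimated correlation). Of 24 STAT3 targets, 12 rose, 16 adjusted over the list alone, with Ccl2 at 2.86 and Cebpd at 1.69 (camera adjusted p = 1.12e-17, and adjusted p = 0.00570 with an estimated correlation). The urokinase list had 9 of 19 risen, 11 adjusted over the list alone, with Serpinb2 at 2.25 and Itga5 at 0.60 (camera adjusted p = 1.41e-09, and adjusted p = 0.104 with an estimated correlation). The Toll-like receptor list had 6 of 24 risen, 8 adjusted over the list alone (camera adjusted p = 2.19e-05, and adjusted p = 0.104 with an estimated correlation).

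With FSL-1, some itch genes rose while no sensory channel or neuronal identity gene passed. Of 31 itch genes, 5 rose, 6 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.356). Nppb was at 1.15 ± 0.16 (adjusted p = 0.00225, edgeR quasi-likelihood), and Osmr, a receptor subunit for interleukin 31, at 0.50 ± 0.08 (adjusted p = 0.00455, edgeR quasi-likelihood). Of 32 sensory neuron ion channels and 28 neuronal identity genes, 0 passed the edgeR test, also adjusted over the list alone, and neither list passed (camera adjusted p = 0.287 and 0.823).

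The largest falls with FSL-1 were genes of stratified epithelium. Krt12, a keratin of the cornea, stood at 33.1, 41.4 and 33.3 CPM in the controls and at most at 0.207 CPM in the treated libraries, a log2 fold change of -8.34 ± 0.25. Krt5, a basal keratin, was 812-fold lower (95% counting interval 224 to 6711), Psca 303-fold lower (103 to 1470), Krt6a 177-fold lower (48.7 to 1468) and Krt6b 154-fold lower (52.5 to 751). Calml3, with 542 counts over the controls and 0 over the treated libraries, was at least 180-fold lower against a floor of 3 counts over the group. In the Pam3CSK4 experiment, Krt12 stood at no more than 0.167 CPM in any library. Of 20 macrophage markers, 1 rose, 2 adjusted over the list alone, with a median of -0.03, a mean of 0.07 and a test that pointed up (camera adjusted p = 0.823). Satellite glia had 2 of 15 fallen (camera adjusted p = 0.0382), fibroblasts 2 of 13 risen (0.0350), Schwann cells 1 of 15 risen (0.356), endothelium 1 of 10 risen (0.592), mural cells 0 of 10 (0.532) and dividing cells 0 of 15 (0.148). With an estimated correlation, the adjusted p of the first 2 were 0.176 and 0.319.

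**Figure D3:**
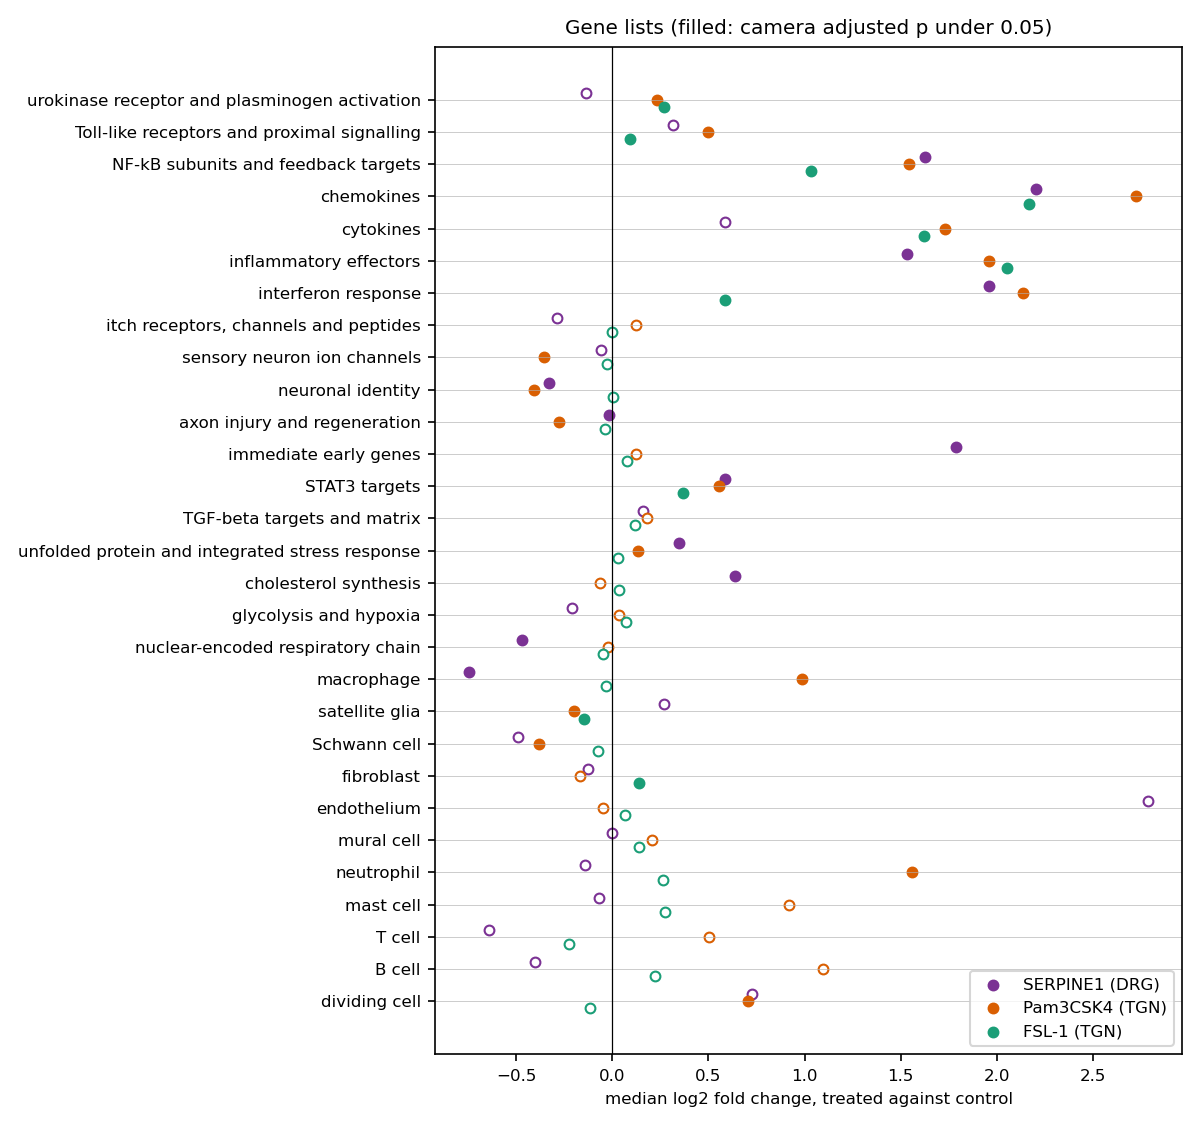
Median log2 fold change of the measured members of each gene list, treated against control, in the 3 comparisons. Filled points passed camera with a preset correlation (adjusted p under 0.05). The inflammatory effector list has medians of 1.53, 1.96 and 2.05 with SERPINE1, Pam3CSK4 and FSL-1.

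Over all 14856 genes tested, 632 rose and 164 fell with FSL-1, and 256 changed by at least 1 log2 unit, 191 upward and 65 downward (edgeR quasi-likelihood, adjusted p under 0.05). The total of 796 was 500 without control 3 and 486 without treated replicate 2. With a block on the replicate number it was 1271, with 823 up and 448 down, and with library totals alone 539 rose and 243 fell.

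The lipopeptides were given at the same dose and time, so their responses could be compared, each against its own controls. Interferon response genes rose more with Pam3CSK4, and 21 of 29 passed the test of the difference in that direction while 0 did in the other. The median difference was 1.04, between medians of 2.13 with Pam3CSK4 and 0.59 with FSL-1 (camera adjusted p = 1.73e-65, and adjusted p = 0.00146 with an estimated correlation). Il1b, at 7.94 with Pam3CSK4, differed by 4.40 ± 0.62 (SE, adjusted p = 0.00480, edgeR quasi-likelihood), and Cfb, complement factor B, stood at 3.42 with Pam3CSK4 against -0.01 with FSL-1 (95% interval of the difference 2.71 to 4.08, adjusted p = 0.000282, edgeR quasi-likelihood). In the other direction, Cxcl5, at 3.34 against 6.84, differed by -3.53 ± 0.24 (adjusted p = 4.96e-05, edgeR quasi-likelihood), and Mmp9, a gelatinase, at 1.94 against 3.75, by -1.84 ± 0.26 (adjusted p = 0.00444, edgeR quasi-likelihood), which did not pass with limma on FPKM (-0.33, adjusted p = 0.215). The 3 largest differences toward Pam3CSK4 were larger than these, at 9.83 for Krt5, 7.66 for Krt12 and 6.13 for Aqp5, and came from falls with FSL-1. The Krt12 call ended without each library but Pam3CSK4-set control 3, Pam3CSK4 replicate 3 and FSL-1 replicate 3 (adjusted p from 0.0533 to 0.958) and the Krt5 call without Pam3CSK4 replicate 1 (adjusted p = 0.0587).

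NF-kB genes differed by a median of 0.50, with 8 higher with Pam3CSK4 and 1 with FSL-1 (camera adjusted p = 1.31e-11, and adjusted p = 0.406 with an estimated correlation). Chemokines differed by a median of 0.65 with 1 gene past the test in each direction, and the list did not pass (camera adjusted p = 0.0853). With a macrophage marker score as a covariate, the medians were 0.17 for NF-kB genes, 0.19 for chemokines, 0.02 for cytokines, 0.09 for inflammatory effectors and 0.84 for interferon response genes. Macrophage markers differed by a median of 0.93 with 0 genes past the test (camera adjusted p = 6.08e-10, and adjusted p = 0.475 with an estimated correlation). Cytokines differed by 0.33 (camera adjusted p = 4.53e-06), inflammatory effectors by 0.48 (0.00115), neuronal identity genes by -0.46 (2.35e-07) and sensory channels by -0.31 (0.00115). With an estimated correlation, the adjusted p of these 4 were 0.406, 0.475, 0.475 and 0.480. The neuronal differences include controls 1 and 2 of the Pam3CSK4 set, where cerebellar neuron markers scored 0.92 and 1.73 against -0.72 in control 3. Over their own measured members, the effectors had medians of 1.96 with Pam3CSK4 and 2.05 with FSL-1, so the sign of that gap differs from the test. Toll-like receptor genes differed by 0.38 (camera adjusted p = 0.000224), dividing cell markers by 0.73 (3.78e-07), stress response genes by 0.19 (0.00834) and fibroblast markers by -0.38 (0.0197), with adjusted p = 0.475, 0.475, 0.475 and 0.585 with an estimated correlation. The dividing cell score was -0.86 and -0.73 in controls 1 and 2 of the Pam3CSK4 set, and 0.43 in control 3, level with the treated libraries (0.33 to 0.45). Itch genes (0.885), urokinase genes (0.465) and STAT3 targets (0.945) did not pass.

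For Plaur no difference was detected, at 0.01 ± 0.19 with a 95% interval of -0.41 to 0.44. Tlr2 differed by 0.48 (-0.35 to 1.31), Serpine1 by 0.14 (-0.42 to 0.69), Plau by 0.75 (-0.06 to 1.56), Tlr1 by 1.29 (0.18 to 2.39) and Tlr6 by 1.04 (0.07 to 2.02). None of these 6 passed after adjustment (adjusted p from 0.210 to 0.978, edgeR quasi-likelihood), and the intervals do not show that the ligands act alike. Without control 3 of the Pam3CSK4 set, Tlr2 (1.06), Tlr1 (1.97), Plau (1.21) and Tlr6 (1.31) passed, with adjusted p of 0.000204, 0.00140, 0.00116 and 0.0441. Without controls 1 and 2 of that set none passed, and the differences were -0.25 for Tlr2, 0.47 for Tlr1, 0.12 for Plau, 0.63 for Tlr6, -0.33 for Plaur and -0.18 for Serpine1 (adjusted p from 0.261 to 0.862), so the sign for Tlr2, Plaur and Serpine1 depends on which controls are kept. Tlr1 also passed with limma on FPKM (1.14, adjusted p = 0.00912).

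**Figure D4:**
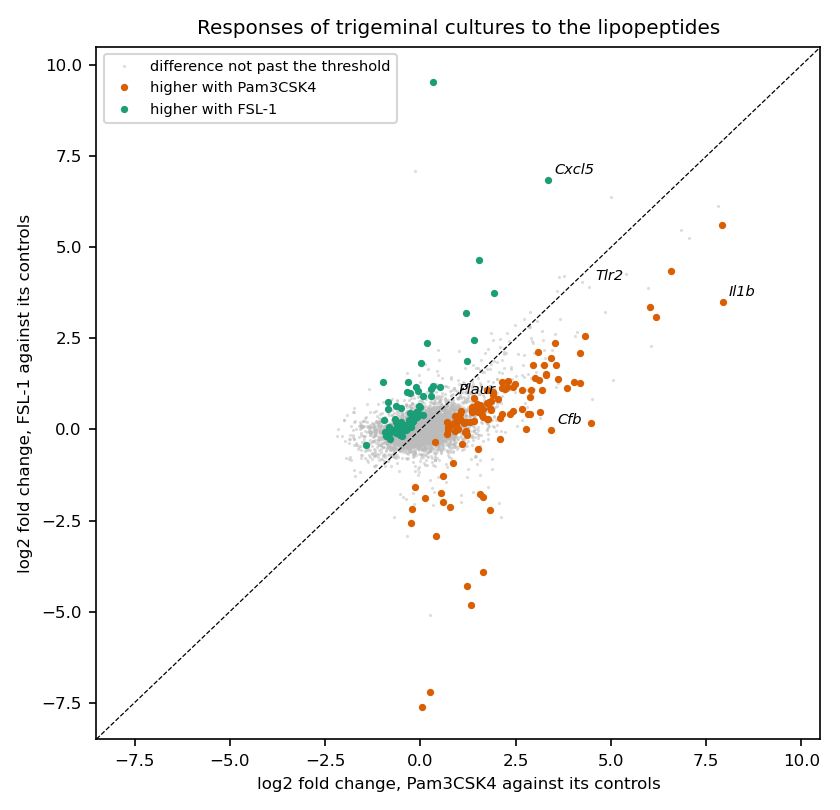
Log2 fold change with FSL-1 against log2 fold change with Pam3CSK4, each against its own controls, with 1 point per gene tested in both single comparisons. Coloured points passed the test of the difference, and the dashed line marks equal responses. In all, 126 genes passed as higher with Pam3CSK4 and 80 as higher with FSL-1. Those not tested in both single comparisons, Krt5 and Krt12 among them, are not drawn.

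Of 15449 genes tested, 206 differed between the lipopeptides, and 108 of these by at least 1 log2 unit (edgeR quasi-likelihood, adjusted p under 0.05). Of the 126 higher with Pam3CSK4, 99 rose with it and 26 fell with FSL-1, 25 of them without a rise with Pam3CSK4. Of the 80 higher with FSL-1, 33 rose with it and 32 fell with Pam3CSK4. Ligand and experiment coincide here, so a difference between the experiments that affects treated and control libraries unequally cannot be told apart from a difference between the ligands. The total was 3335 without control 3 of the Pam3CSK4 set, 114 without its control 1 and from 86 to 109 without any 1 Pam3CSK4 library. It was 88 and 89 without FSL-1 controls 2 and 3, from 84 to 119 without any 1 FSL-1 library, 610 with DESeq2 and 53 with the macrophage covariate.

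The 3 responses shared many risen genes. Of the genes risen with Pam3CSK4 and with FSL-1, 359 were shared, where independent lists would share 36.9 (Fisher's exact p = 2.96e-299), and 57 of them were higher with Pam3CSK4 and 6 with FSL-1 by the test of the difference. SERPINE1 shared 392 risen genes with Pam3CSK4, where independent lists would share 225 (Fisher's exact p = 8.32e-37), and 322 with FSL-1, where they would share 167 (Fisher's exact p = 1.62e-41). In all 3 comparisons 222 genes rose, among them Acod1, Nos2, Tnf, Cxcl2, Il1b, Tlr2 and Rsad2. If all 3 lists were independent they would share 9.64, but the excess over this number includes the overlap between the lipopeptides. Of 350 genes risen with both lipopeptides, 222 rose and 18 fell with SERPINE1. For scale, 3866 of the 14392 genes tested with both SERPINE1 and Pam3CSK4 rose with SERPINE1. By edgeR, fallen genes of SERPINE1 were shared less often than independent lists would be, at 58 with Pam3CSK4 (odds ratio 0.571, Fisher's exact p = 4.05e-05) and 16 with FSL-1 (odds ratio 0.457, Fisher's exact p = 0.00199). With DESeq2 the deficit was absent for Pam3CSK4, at 217 where independent lists would share 208 (Fisher's exact p = 0.473), and remained for FSL-1, at 29 where they would share 43.1 (Fisher's exact p = 0.0163). With a log2 fold change of at least 1, 1 fallen gene was shared in each pair, where independent lists would share 0.369 and 0.266 (Fisher's exact p = 0.310 and 0.235), too few to show a deficit. The lipopeptides shared 32 fallen genes, where independent lists would share 3.90 (Fisher's exact p = 1.10e-20), and 0 with a log2 fold change of at least 1. With a log2 fold change of at least 1, the shared risen genes numbered 151, 182, 109 and 100 in place of 359, 392, 322 and 222. Genes are not independent replicates, and whether the SERPINE1 response differs from those of the lipopeptides was not tested, as ganglion and experiment differ with the ligand.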

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

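The tests of the macrophage share with SERPINE1, of a bacterial ligand and of other splits of the libraries were chosen only after the results were seen.

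The number of genes whose response differed between the lipopeptides, 206, stood out because a test of the difference between the groups passed. In 6 of 100 relabellings within each experiment, the real labels included, at least as many genes were called, and the highest other relabelling called 2392. The 5 others all kept the real Pam3CSK4 labels and changed only the FSL-1 labels, so none of them arose where both experiments were relabelled. They still held the Pam3CSK4 response and do not stand for the absence of a difference. This share therefore cannot decide on chance, which is not excluded for this number. The relabelling with 2392 calls points to a structure of the samples: it exchanged FSL-1 libraries and controls, which adds the responses in place of subtracting them. The single comparisons allow 10 splits each, too few for a share under 0.05. The real split, which was the 1 split with as many genes in each, called 7267 genes with SERPINE1, where the highest other called 228. That other split set controls 2 and 3 and treated replicate 3 against the remaining libraries. The real split called 1328 with Pam3CSK4 and 796 with FSL-1, where the highest other called 0.

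The larger interferon response to Pam3CSK4 than to FSL-1 may follow from the share of macrophages in the cultures. With a macrophage marker score as a covariate, the median difference of the interferon list was 0.84 in place of 1.04, a share of 0.808 with an SD of 0.0750 over resampled list members, and 13 of 29 genes passed in place of 21. This value lies above the upper bound, set for no macrophage source, by less than that SD, so a macrophage part stays open. It lies above the lower bound, set for macrophages as the cause, by more than that SD. The SD covers list members and not libraries. Within the Pam3CSK4 experiment the score was also higher in the treated libraries (0.49 to 0.66) than in their controls (at most 0.16). The covariate is thus not separate from treatment, and this test cannot decide how much of the list's difference comes from macrophages. The medians of the NF-kB and chemokine lists went from 0.50 to 0.17 and from 0.65 to 0.19, so macrophages stay an open explanation for them. The macrophage markers were also higher in the Pam3CSK4 controls than in the FSL-1 controls, by a median of 1.57 on the log2 scale and for 20 of 21 markers, and ligand structure, culture and experiment cannot be told apart in this design.

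The rise of inflammatory genes with SERPINE1 came with a trend over transcript length and with a number of calls far above that of the lipopeptides. The tables argue against the length trend as the whole source of the rise, since the median of the inflammatory lists kept a share of 0.961 (SD 0.0479) of its size, from 1.61 to 1.55. They argue against it as the whole source of the number of calls as well, with 7150 genes called after the correction in place of 7267. The genes called changed in part, as 76.6% of the calls kept their direction and call. The tables also argue against more macrophages in the treated cultures, since the macrophage markers had a median of -0.74 (SD 0.43), far below that rise. That fall comes from treated replicates 1 and 2, with macrophage scores of -1.02 and -0.71, where Tnf still stood at 11.2 and 14.3 CPM, while replicate 3, with the highest Tnf, scored 0.58, so macrophages stay open for the larger rise in replicate 3. A bacterial ligand carried with the protein stays open, because the 222 genes risen in all 3 comparisons could come from it as well as from SERPINE1 acting through TLR2, and the labels name no library with a control protein.

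Transcripts of tissues outside the ganglion were found in both trigeminal experiments, with the largest marker scores in control libraries. Contamination of the cultures by such tissue may be their source. High scores were not confined to controls. The epithelial score was 0.28 to 0.64 in the Pam3CSK4 libraries and -0.76, -0.64 and 0.08 in their controls. The cerebellar score was 0.42 to 0.50 in the SERPINE1 libraries and -0.59 to -0.35 in their controls. For the Pam3CSK4 set, 5 held-out cerebellar genes had a median log2 ratio of 2.03 (SD 0.98) in controls 1 and 2 over the treated libraries, with 4 of 5 above in both. This met the bound set before, but by less than that SD. The 9 held-out muscle genes had a median of 1.69 (SD 0.15), 9 of 9 above, short of the bound, and in control 3 the median was -0.00. The level of Acta1, the skeletal muscle actin, was 498, 626 and 198 CPM in the controls and 145 to 159 CPM in the treated libraries. In the FSL-1 experiment Acta1 was at most 3.62 CPM in any library, so muscle transcripts were not confined to the controls of the Pam3CSK4 set. Their level in the treated libraries lowers the ratio taken against those libraries. For the FSL-1 controls, 12 held-out epithelial genes had a median of -0.54 (SD 0.74) in treated over control libraries, with 7 lower in every treated library, so epithelium stays open, and an effect of FSL-1 on these genes was not tested apart from it.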

How the results depend on the processing

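The length and GC corrections, FPKM without a filter, the pairs of libraries left out and the macrophage covariate were added after the data were seen. The number of genes called with SERPINE1 stayed within 1.5 times 7267 under every alternative run, from 5324 to 9944, the latter without control 1 and treated replicate 3. After the length correction 76.6% of its calls kept their direction and call. With Pam3CSK4, DESeq2 called 2264 genes in place of 1328, the fit of 12 libraries 3539, and leaving out 1 replicate gave 384 to 5491. Without its controls 1 and 2 the number was 1845. With FSL-1, the replicate block called 1271 genes in place of 796, and leaving out 1 replicate gave 486 to 809. For the difference, DESeq2 called 610 genes in place of 206, the macrophage covariate left 53, and leaving out 1 replicate gave 84 to 3335. The causes were not tested. Simulated data gave more false calls with DESeq2. The fit of 12 libraries lowered the number with FSL-1 from 796 to 563. With a log2 fold change of at least 1, the shared risen genes numbered 182 (SERPINE1 and Pam3CSK4), 109 (SERPINE1 and FSL-1), 151 (both lipopeptides) and 100 (all 3), by construction fewer. A pseudocount of 1 on FPKM shrank the folds of genes with few counts, by construction as well. With an estimated correlation, 0 lists passed for SERPINE1 in place of 12, 5 in place of 17 for Pam3CSK4, 6 in place of 10 for FSL-1 and 1 in place of 11 for the difference, where fry also left 1. In the single comparisons fry kept most list calls. With it, 2 lists lost and 6 gained a call for SERPINE1, 6 lost and 1 gained a call for Pam3CSK4, and 1 gained a call for FSL-1. Among named genes, 1 reversed: Plau with SERPINE1 was at -0.29 without control 1 and treated replicate 3, in place of 0.06, and the cause was not tested. Of the named genes called, 91 of 100 with SERPINE1 kept their call without any 1 replicate, 37 of 77 with Pam3CSK4, 51 of 66 with FSL-1 and 8 of 12 for the difference. Replicate numbers did not pair the libraries: same-number deviations from the group means correlated across genes at 0.431, -0.305 and 0.395 with SERPINE1, at 0.00725, 0.0119 and 0.0555 with Pam3CSK4 and at 0.266, 0.124 and -0.0788 with FSL-1. With SERPINE1 a split crossed the groups: control 1 went with treated replicates 1 and 2 (0.431 and 0.415), and controls 2 and 3 with treated replicate 3 (0.427 and 0.395). Control 1 and treated replicate 3 correlated at -0.561. This split was not fitted as a block. Without control 1 and treated replicate 3 it coincides with treatment, so the 9944 calls and the Plau value of that setting cannot be told apart from it. In simulations with 200 changed genes, changes of 1.5 fold were recovered in 14.9%, 27.7% and 64.2% of cases (SERPINE1, Pam3CSK4 and FSL-1 designs). These simulations gave 122, 141 and 182 calls, against 7267, 1328 and 796 in the real comparisons. The Benjamini-Hochberg cut depends on the number of calls, so these shares do not measure recovery in the real comparisons. Small changes that did not pass are not shown to be absent.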

Other observations

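Every list test in this section was set in advance, and of the genes in this section only Spaca6, Gm20594 and Lyz2 were chosen after their values were seen. Glycolysis and hypoxia genes moved both ways with SERPINE1. Of 23 measured, 7 rose and 9 fell, 7 and 10 adjusted over the list alone, with Ndrg1 at 1.44 and Hk2, a hexokinase, at 1.17 among the risen and Tpi1, a glycolytic enzyme, at -0.62 among the fallen. The list did not pass, and its median of -0.21 and mean of 0.07 differed in sign (camera adjusted p = 0.125). TGF-beta targets and matrix genes had 10 of 25 risen and 3 fallen, also adjusted over the list alone, with Bhlhe40 at 2.03, and did not pass (camera adjusted p = 0.276). Sensory neuron ion channels had 2 of 35 risen and 4 fallen, 1 and 1 adjusted over the list alone (camera adjusted p = 0.153), but 0 risen and 13 fallen with a median of -0.35 in place of -0.06 after the length correction. The Toll-like receptor list had 10 of 22 risen, also adjusted over the list alone (camera adjusted p = 0.328), and 5 risen and 2 fallen with a median of 0.12 in place of 0.32 after that correction. The urokinase list had 2 of 18 risen and 3 fallen, also adjusted over the list alone (camera adjusted p = 0.176). The fallen were Plaur, Anxa2 at -0.71 and S100a10 at -0.60, of which the latter stood at -0.15 (adjusted p = 0.284) after the length correction.

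In the trigeminal cultures, Slc7a11 rose with Pam3CSK4 by 2.69 and with FSL-1 by 1.77, and the stress response list had 4 of 23 risen, and 1 risen and 1 fallen of 23 (camera adjusted p = 0.00240 and 0.495, and adjusted p = 0.250 with an estimated correlation for Pam3CSK4). The immediate early list, with 23 of 29 risen after SERPINE1, had 4 of 28 risen and 1 fallen with Pam3CSK4 and 5 of 29 risen with FSL-1, and passed in neither (camera adjusted p = 0.333 and 0.148). Cholesterol synthesis genes (camera adjusted p = 0.513 and 0.532), respiratory chain genes (0.562 and 0.287), glycolysis and hypoxia genes (0.674 and 0.495) and TGF-beta targets (0.147 and 0.0584) did not pass with Pam3CSK4 or FSL-1. The axon injury list had 2 of 26 fallen with Pam3CSK4 (camera adjusted p = 0.0340, and adjusted p = 0.370 with an estimated correlation) and did not pass with FSL-1 (0.829). Neutrophil, mast cell, T cell and B cell markers, with at most 5 measured members each, had 1 neutrophil, 1 T cell and 1 B cell marker risen with Pam3CSK4, 1 B cell marker risen with SERPINE1 and 0 with FSL-1 by edgeR. With SERPINE1 the B cell list had a median of -0.40 and a mean of 0.66, and mural cells a median of -0.00 and a mean of 0.05. For the difference between the lipopeptides, STAT3 targets (median 0.03), respiratory chain genes (-0.01) and mural cells (0.10) had a median of the other sign than the test.

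Some genes differed with SERPINE1 by a similar amount in every treated library. Spaca6, chosen after its values were seen, stood at 1.40, 1.10 and 1.10 CPM in the controls and at 32.6, 32.7 and 31.5 CPM in the treated libraries. Gm20594, chosen likewise, stood at 356, 365 and 264 CPM in the controls and at 62.5, 67.8 and 59.6 CPM in the treated libraries. Muc2, an intestinal mucin and 1 of the 8 largest rises, stood at 0.443 ± 0.273 CPM in the controls and at 13.4 ± 1.19 CPM in the treated libraries (SD, n = 3). By contrast Lyz2, the macrophage lysozyme, also chosen after its values were seen, stood at 252, 612 and 574 CPM in the controls and at 131, 167 and 471 CPM in the treated libraries, so that control 1 and treated replicate 3 stood apart from their groups.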
